A study of Zea mays with 2 samples.

How the data were processed

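Small RNA libraries were made from total RNA of developing cobs with an Illumina small RNA protocol and sequenced on an Illumina GAII, per the labels' protocols. The deposited files give 1 table per library with each distinct sequence of 18 to 31 nt and its count of reads, and the counts were whole numbers of at least 1 with no sequence listed more than once. Counts were not normalized by the authors as far as the deposited values show. How adapters were removed, which filters were used and whether reads were matched to a genome are not given in the sources used here. Each file held a sequence column and a count column, with 0 other columns.

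Libraries were grouped by genotype from the labels: 1 mutant library (rmr2-1/rmr2-1) and 1 non-mutant library (Rmr2/rmr2-1). Total counts were 6521543 and 33671756 reads. A count of 0 allows up to 3 reads, which is 0.460 RPM in the mutant and 0.0892 in the non-mutant library. Reads of 18 to 30 nt served as the total for shares and for reads per 1000000 (RPM). Shares of a library were given with Wilson 95% intervals. Ratios between libraries were given with exact conditional binomial 95% intervals, and a sequence or family was counted as higher or lower when the whole interval lay beyond 2-fold. The ratio of 24-nt to miRNA reads had an interval from the counting variance of its logarithm. No test across genotypes was made, because there was 1 library of each.

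miRNA families were matched by the first 18 bases of mature sequences listed before the data were examined, in lists of development, nutrient stress, silencing machinery and anther phased siRNA triggers, with tasiR-ARF kept apart from the miRNA sums. Named were, by a rule also fixed before, every family with at least 50 reads over both libraries and the 5 most abundant 24-nt sequences of each library. The median log2 ratio of a list was placed among 10000 random lists drawn from 18690 groups of other 20 to 22 nt sequences that share their first 18 bases, each member drawn from the 50 groups nearest in mean abundance; a count of 0 entered these medians as 3 reads. Lists matched on non-mutant abundance alone were added after the data were examined. For distinct sequences, non-mutant reads were thinned at random to the mutant depth, with the mean of 10 draws reported. For sequences expected but absent, and for classes of abundance, the non-mutant library was split at random into 2 parts of like size, of which 1 chose the sequences and the other was compared with the mutant library. The sum for overlapping sequences took every read that shared 18 consecutive bases with the named sequence.

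Ribosomal fragments were reads lying wholly within a 5.8S sequence of 129 nt or a 5S sequence of 119 nt, typed from background knowledge after the data were examined; reads covered 125 and 117 of these bases. Reads of the 5′ adapter were those sharing 10 consecutive bases with it, with the reversed adapter as the control. Shares were standardised over strata of GC content or of the first base and the last 2 bases, each stratum weighted by its mean share over both libraries. Error rates were estimated from reads 1 substitution away from 25 abundant sequences, leaving out the highest 10% of neighbours.

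The interval and the 2-fold rule were tested on simulated counts for 18712 groups of 20 to 22 nt sequences with the same means and depths. Of 200 groups changed 4-fold, 69% were counted beyond 2-fold in the right direction. Of the unchanged groups, 1 was counted. The intervals held the true ratio in 96.2% of groups. The counts were drawn from Poisson distributions, without PCR duplicates or differences between separately made libraries. The simulation therefore checks the intervals for counting error alone and does not give the rate of false counts in these data.

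Alternatives fixed before the data were examined used other totals, other references, other rules for matching miRNAs and distinct sequences in place of reads. Later additions left out adapter and ribosomal reads or the 1000 most abundant sequences, standardised for GC content or end bases, thinned to equal 24-nt reads (also for sequences of at least 2 reads), or scaled families to miRNA reads other than miR166. Comparisons that need a genome (genome-matched reads, windows along chromosomes, reads near genes and removal of all structural RNA) were not analysed here. In the gene table of assembly Zm-B73-REFERENCE-NAM-5.0, rmr2 is a synonym of LOC100381913, a protein-coding gene. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.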

Results

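Small RNAs were sequenced from developing maize (Zea mays) cobs of 4 cm, collected before flowering, from plants homozygous for the mutant allele rmr2-1 and from their non-mutant Rmr2/rmr2-1 siblings. The gene rmr2 (required to maintain repression2) takes part in paramutation, a heritable change in the expression of an allele directed by another allele, and all plants carried the repressed Pl' state of the purple plant1 gene on both chromosomes in a mostly K55 background. Each genotype was measured in 1 library, and the labels give 2 plants per genotype without saying whether their RNA was pooled. The files list each distinct sequence with its number of reads. The mutant library held 6521543 reads of 2489897 distinct sequences, and the non-mutant library held 33671756 reads of 17486323 distinct sequences. Reads of 18 to 30 nt numbered 6518268 in the mutant and 33646005 in the non-mutant library, and levels of single sequences are given per 1000000 of them (RPM). By this number the non-mutant library was 5.16-fold deeper. With 1 library per genotype there was no replicate error and no test of the genotypes, and every difference below is between these libraries. Intervals are 95% intervals for counting error alone, since PCR reads without molecular identifiers are not independent molecules. Small RNA reads do not measure the rmr2 transcript, so the genotype of a library was taken from its label.

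The first question was how the small RNA size classes of mutant cobs compared with those of non-mutant cobs. The 24-nt class, which in plants consists mostly of siRNAs of transposons and other repeats that guide DNA methylation, was the largest class in both libraries and was smaller in the mutant. It made up 50.68% of 18 to 30 nt reads in the mutant library (Wilson interval 50.64 to 50.72%) and 69.26% in the non-mutant library (69.25 to 69.28%), a ratio of 0.732 (0.731 to 0.733). The 22-nt class, a second abundant siRNA class of maize, showed the opposite difference, with 29.44% of reads in the mutant (29.41 to 29.48%) and 14.38% in the non-mutant library (14.36 to 14.39%), a ratio of 2.05 (2.04 to 2.05). The 21-nt class, which contains most miRNAs and the trans-acting siRNAs, made up 9.31% (9.29 to 9.34%) and 5.31% (5.30 to 5.31%) of reads, a ratio of 1.76 (1.75 to 1.76). Set against each other, there were 58.1 reads of 22 nt per 100 reads of 24 nt in the mutant library and 20.8 in the non-mutant library.

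Of the other classes, those of 18 and 19 nt were lower in the mutant library, with ratios of 0.617 and 0.844. The 23-nt class followed the 24-nt class and was lower in the mutant, at 5.59% against 7.22% of reads. The 20-nt class was nearly equal, at 0.903% and 0.894%, and so was the 25-nt class, at 2.04% and 2.10%. Reads of 26 to 30 nt made up 1.80% of the mutant and 0.560% of the non-mutant library, a ratio of 3.22 (3.20 to 3.24). Each length from 26 to 30 nt was higher in the mutant, with ratios from 1.70 at 30 nt to 4.15 at 27 nt. Fragments of 5.8S ribosomal RNA were 10.1-fold more frequent in the mutant library (9.78 to 10.4), at 1925 against 191 RPM, and fragments of 5S ribosomal RNA were 2.60-fold more frequent (2.44 to 2.77). Together the fragments of these 5.8S and 5S sequences were a small part of either library. 5.8S fragments made up 0.193% of the mutant and 0.0191% of the non-mutant reads, and 5S fragments 0.0228% and 0.00878%. Fragments of other ribosomal and structural RNA were not counted, so the whole share of such fragments is not known.

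**Figure D1:**
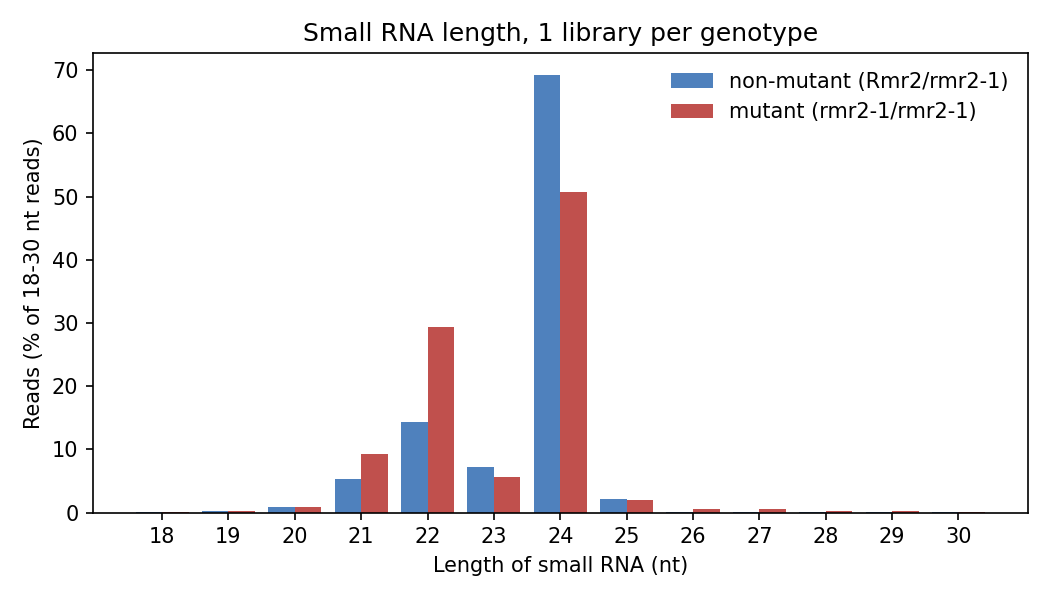
Length distribution of small RNA reads in the mutant (rmr2-1/rmr2-1) and non-mutant (Rmr2/rmr2-1) cob libraries; the x axis is the read length in nt, the y axis is the percent of 18 to 30 nt reads, and each bar is 1 library. The 24-nt bar is 50.68% in the mutant and 69.26% in the non-mutant library, and the 22-nt bar is 29.44% and 14.38%.

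Reads of the mutant library were richer in G and C. Mean GC content was 61.1% in the mutant and 58.8% in the non-mutant library for 24-nt reads, 59.8% and 56.7% for 22-nt reads, and 59.3% and 56.4% for 21-nt reads. The size classes were therefore also compared within strata of 5% GC content. In all 14 strata that held at least 1000 reads in both libraries, the 24-nt share was lower and the 22-nt share higher in the mutant library. In the stratum starting at 50% GC, for example, 51.0% of mutant and 73.8% of non-mutant reads were 24 nt long, and 37.1% and 16.9% were 22 nt long.

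**Figure D2:**
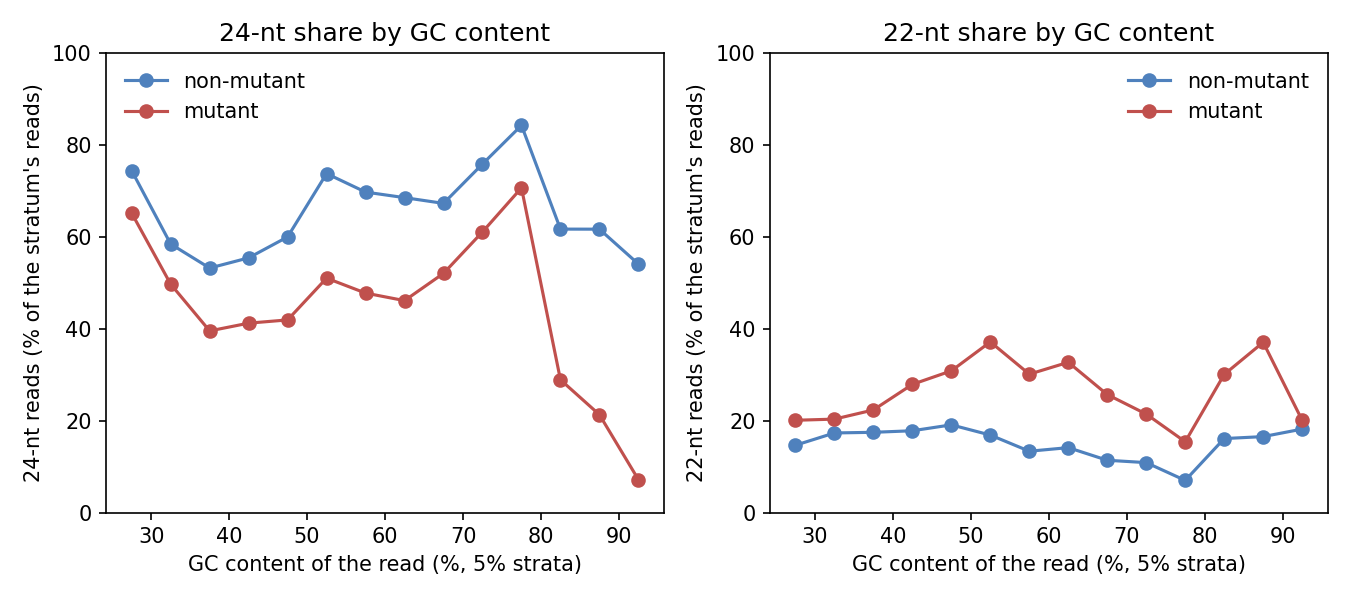
Share of 24-nt reads (left) and of 22-nt reads (right) by GC content of the read, in strata of 5% that hold at least 1000 reads in both libraries; the x axis is the GC content in percent, the y axis is the percent of the stratum's reads, and each line is 1 library. The 24-nt share is lower and the 22-nt share higher in the mutant library in all 14 strata.

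Because shares of a library sum to a fixed total, 24-nt reads were also set against reads of listed conserved miRNA families. The mutant library had 29.5 reads of 24 nt per miRNA read and the non-mutant library 88.5, a log2 ratio of -1.59 (-1.60 to -1.58). Most of this distance rested on 1 family, miR166: without it the values were 68.6 and 103.9 and the log2 ratio was -0.60 (-0.61 to -0.58). The direction was the same with either reference, and with the median ratio of families as the reference (log2 ratio -0.58). Some single families had lower ratios than the 24-nt class, and against those alone the direction would reverse.

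miRNA families were compared to ask whether the libraries also differed in small RNAs outside the siRNA classes. Of 27 listed miRNA families, 17 had at least 50 reads over both libraries. By RPM, 6 of these 17 were more than 2-fold higher in the mutant library over their whole interval, 2 were more than 2-fold lower, and 9 were neither. The minimum counts raw reads, so the deeper non-mutant library meets it at a lower RPM. Both lower families, miR162 and miR827, passed it mainly on non-mutant reads. Without a minimum 7 were higher and 2 lower, the added family being miR408 with 6 mutant and 2 non-mutant reads (ratio 15.5, 2.77 to 157). Listed miRNAs made up 1.72% of mutant and 0.782% of non-mutant reads, and miR166 alone accounted for 57.0% and 14.7% of them. Scaling to miRNA reads in place of all reads shifts every log2 ratio by -1.14, largely because of miR166. The split then becomes 3 families higher (miR160, miR166 and miR319) and 8 lower, and the ratios of miR159, miR167 and miR396 pass from above to below 1. Scaled to miRNA reads other than miR166, a total whose own log2 ratio was 0.15, the split is 6 higher and 4 lower, and among these 3 families miR396 alone passes below 1.

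Among the 16 families of the developmental list, 14 had at least 50 reads, of which 5 were higher and none was lower by the 2-fold rule. Scaled to miRNA reads, 3 were higher and 6 lower, and scaled to miRNA reads other than miR166, 5 were higher and 2 lower. miR166, which targets class III HD-ZIP transcription factors of organ polarity and the meristem, was 8.49-fold higher in the mutant library (8.39 to 8.60), with 9797 against 1154 RPM. miR160, which targets auxin response factors, was 12.9-fold higher (10.8 to 15.4), at 70.1 against 5.44 RPM. miR319, which targets TCP transcription factors, was 5.92-fold higher (5.68 to 6.17). miR169, which targets NF-YA transcription factors, was 3.24-fold higher (3.13 to 3.36), and miR164, which targets NAC transcription factors, was 2.72-fold higher (2.40 to 3.09). Scaled to miRNA reads, miR164 and miR169 had log2 ratios of 0.31 and 0.56 and were no longer counted as higher. With miR166 left out of the scale they were counted, with log2 ratios of 1.30 and 1.55.

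By RPM, other developmental families stayed within or near 2-fold. Scaled to all listed miRNA reads, miR171, miR172, miR390 and miR394 were counted as lower, with log2 ratios of -1.14, -1.34, -1.91 and -1.37, and they were not counted when miR166 was left out of the scale. miR172, which targets APETALA2-like factors of inflorescence development, was the most abundant listed family in the non-mutant library, with 3257 RPM against 2836 in the mutant, a ratio of 0.871 (0.857 to 0.884). miR394 had a ratio of 0.847 (0.832 to 0.863), miR171 a ratio of 0.997 (0.931 to 1.07) and miR396 a ratio of 1.06 (0.790 to 1.39). miR159 had a ratio of 1.14 (1.08 to 1.20) and miR167 a ratio of 2.06 (1.91 to 2.23) by RPM. Scaled to miRNA reads their log2 ratios were -0.95 and -0.09, and scaled to miRNA reads other than miR166 they were 0.04 and 0.90. miR156, which targets SPL transcription factors of phase change, had a ratio of 0.450 (0.401 to 0.505), and miR444, which targets MADS-box factors, had a ratio of 0.461 (0.391 to 0.541). Both intervals include a 2-fold difference, so neither was counted by RPM, while both were counted as lower when scaled to miRNA reads, with or without miR166. miR390, which triggers trans-acting siRNAs from TAS3 transcripts, had a ratio of 0.583 (0.446 to 0.752), and its product tasiR-ARF, a siRNA against auxin response factors, had a similar ratio of 0.585 (0.561 to 0.609). miR393 and miR529 had fewer than 50 reads, with 0 reads each in the mutant library.

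Of the families that act on the silencing machinery, 1 was higher and 1 lower. miR168, which targets ARGONAUTE1, was 4.60-fold higher in the mutant library (4.31 to 4.91), at 266 against 57.8 RPM, but was not counted when scaled to all listed miRNA reads, with a log2 ratio of 1.06. With miR166 left out of the scale its log2 ratio was 2.05 and it was counted as higher. miR162, which targets DICER-LIKE1, had 14 reads in the mutant and 261 in the non-mutant library and was 3.61-fold lower in the mutant (2.11 to 6.70). Matched by its full listed sequence it had fewer than 50 reads and was not counted, because nearly all of its reads were another form, TCGATAAACCTCTGCATCCAG, with 14 and 250 reads and a ratio of 0.289 (0.156 to 0.494). Among 7 families of nutrient stress, only miR827, which targets SPX-domain genes of phosphate response, reached 50 reads. It had 0 reads in the mutant and 77 in the non-mutant library, at least 4.97-fold lower in the mutant against the 3 reads that a count of 0 allows, and the limit of its exact interval was 3.95-fold. The triggers of phased siRNAs of anthers were nearly missing, with 2 and 0 reads of miR2118 and no read of miR2275 in these cobs.

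**Figure D3:**
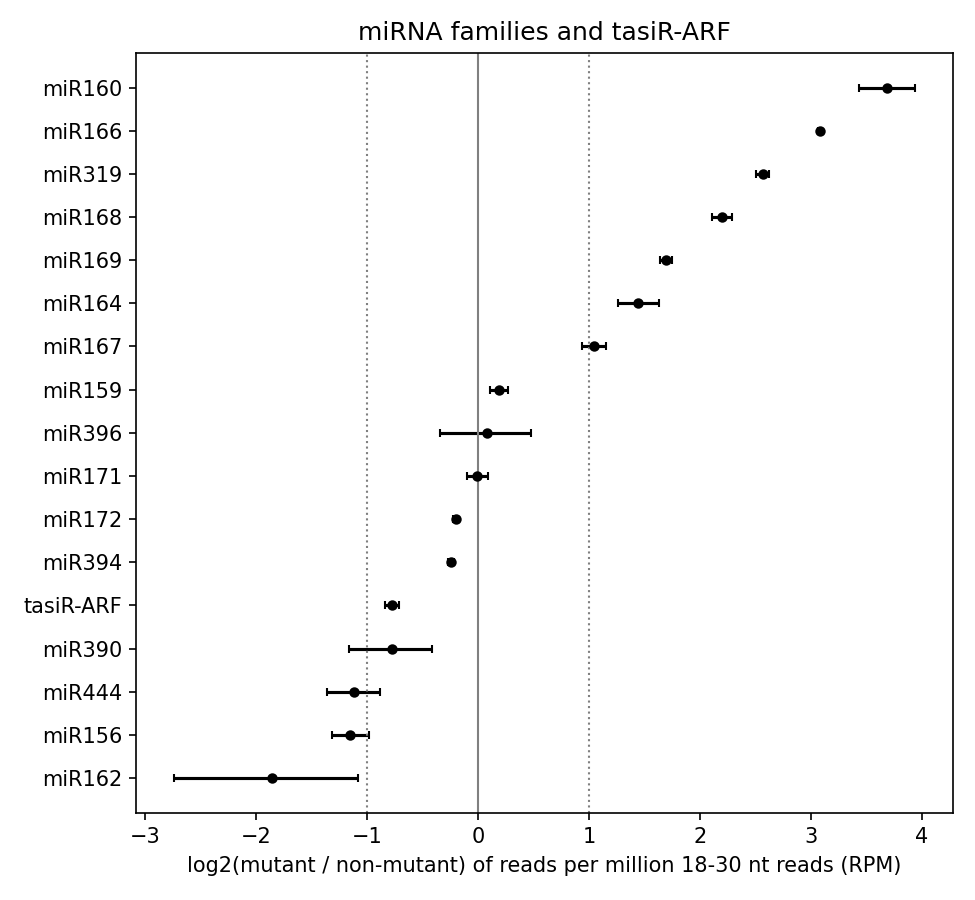
Ratio of RPM (reads per 1000000 reads of 18 to 30 nt), mutant over non-mutant library, on a log2 axis for 16 miRNA families and tasiR-ARF with at least 50 reads over both libraries and at least 1 in each; points are the ratios, bars are 95% counting intervals, and dotted lines mark 2-fold. miR160 at 3.69 and miR166 at 3.09 lie farthest to the right and miR162 at -1.85 farthest to the left, and scaling to miRNA reads shifts all points of miRNA families by -1.14, which takes miR159, miR167 and miR396 below 0.

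The median log2 ratio of the 17 families was 0.08, with miR827 placed at its bound. Random lists of other 20 to 22 nt sequences of like abundance had a median of 2.52 (95% of lists between 1.45 and 3.50), and the miRNA median lay at percentile 0 of 10000 lists. The developmental families had a median of 0.13, also at percentile 0, and the silencing pair a median of 0.17, at percentile 6.49. miR827, the single nutrient family, had a bound of -2.31, at percentile 34.4, and the random median for this list was also -2.31. Matching on the mean of both libraries favours sequences that are abundant in the mutant, and all 18690 groups of other sequences had a median of 0.64. With lists matched on non-mutant abundance alone, a comparison added after the data were seen, the random median was 0.42 and the 17 families lay at percentile 27.7, the developmental families at 21.7, the silencing pair at 50.3 and miR827 at 17.5. The low percentiles of the miRNA families and the silencing pair therefore depended on how the lists were matched. Matching on the non-mutant library selects the opposite way, toward sequences abundant there, so neither percentile is free of the choice. The lead sequences of miR160, miR164, miR166, miR168 and miR390 had 61.9% GC, and those of miR172 and miR827 had 38.1%.

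Distinct sequences were compared to ask how many different siRNAs each library contained. At equal depth, the mutant library held 1615343 distinct 24-nt sequences and the thinned non-mutant library 3137062, a ratio of 0.515. The mutant library also held fewer distinct sequences in each other class from 20 to 25 nt, with ratios of 0.574 at 20 nt, 0.760 at 21 nt, 0.494 at 23 nt and 0.774 at 25 nt. For 22 nt the ratio was 0.942, so that the larger number of 22-nt reads in the mutant came with slightly fewer sequences. With equal numbers of 24-nt reads the mutant count was 32.4% lower, although the direction depended on single-read sequences. The mutant library held 340745 sequences of at least 2 reads, against 417257 in the non-mutant library thinned to equal 18 to 30 nt reads and 297371 in that library thinned to equal 24-nt reads. Of 53613 sequences of 24 nt expected at 3 to 6 reads from a part of the non-mutant library, 65.5% had no read in the mutant library, against 4.46% in the other part of the non-mutant library, which differs from the first by sampling alone. Among 22-nt sequences chosen in the same way these values were 42.8% and 9.16%, and among 21-nt sequences 41.2% and 7.39%.

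Reads of the mutant library were concentrated on fewer sequences. The 100 most abundant sequences took 19.3% of 22-nt reads in the mutant and 8.00% in the non-mutant library, 32.2% and 17.8% of 21-nt reads, and 3.77% and 1.12% of 24-nt reads. Among 1606 sequences of 24 nt with a mean of at least 10 RPM, 1155 were more than 2-fold higher in the mutant library over their whole interval and 284 more than 2-fold lower. Of 2287 such 22-nt sequences, 1601 were higher and 83 lower, and of 558 such 21-nt sequences, 409 were higher and 13 lower. The 1606 abundant 24-nt sequences held 11.9% of the mutant and 2.83% of the non-mutant 24-nt reads. Each of these sets, also those of 22 and 21 nt, was chosen by the mean over both libraries, which favours the library whose reads are more concentrated. The counts of higher sequences therefore do not measure how many siRNA reads each class held. Only 24-nt sequences were also classed in another way. Classed instead by their reads in a random part of the non-mutant library, 24-nt sequences were lower in the mutant in all 7 classes of abundance, with ratios between 0.552 and 0.836. The 7 classes together hold all 24-nt reads, so their ratios must average to that of the whole 24-nt class. Setting classes by the non-mutant library also selects the opposite way, toward sequences abundant there, so neither choice is neutral.

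The 5 most abundant 24-nt sequences of each library differed, and no sequence was in both lists. No genome was used here, so their places in it were not analysed. In the non-mutant library the most abundant was AGCTGTTTGGATTGCTGCAGCTGC, with 615 RPM, against 13.7 in the mutant, 45.1-fold lower (36.6 to 56.1). Its close relative AGCTGTTTGGACTGCTGCAGCTGC was 43.7-fold lower in the mutant (33.6 to 58.1), and ACAAGCCGACACTGTTGCAGCTGT was 21.9-fold lower (18.3 to 26.5). The remaining sequences, ACTGACTCTGCGCACGCGCGGACC and AGGGCTGCTACCCTAGAACCAAGC, had ratios of 0.559 (0.525 to 0.596) and 0.870 (0.816 to 0.928). In the mutant library the most abundant was GTGTACTCTAATGAGCTGGACGCA, with 786 against 65.1 RPM, 12.1-fold higher (11.5 to 12.7). AGGCGGATTAAGGCATCCTGGCCG was 81.5-fold higher (72.2 to 92.3), GTGGCGTTGGTCTCCTGGGCACGG 32.5-fold higher (29.9 to 35.3), CCTGGACACCAGGATGTCTGGATG 21.8-fold higher (20.04 to 23.64) and CAGCCCCGCGTCGCACGGATTCGT 15.8-fold higher (14.73 to 17.03).

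The other reads that overlapped each of these by at least 18 bases, the named sequence left out, differed in the same direction for all 10. Their ratio was between 0.0483 and 0.481 for the sequences of the non-mutant library and between 4.70 and 21.5 for those of the mutant library. The 10 sequences were chosen as the most abundant of each library, which favours these directions. Reads that share 18 bases with a named sequence can include its length variants and its copies with sequencing errors. The shared direction is therefore not independent evidence for the differences of the named sequences. With the named sequence included, for the 3 sequences of the non-mutant library with the strongest difference, 97.9%, 96.3% and 91.5% of overlapping non-mutant reads were 24 nt long. For CAGCCCCGCGTCGCACGGATTCGT and CCTGGACACCAGGATGTCTGGATG, only 12.8% and 15.3% of overlapping mutant reads were 24 nt long, so that these came from sets of mixed length.

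The 22-nt sequences named here were chosen after their values were seen. The most abundant in the mutant library, TGCTCGTACGAAGAGGGCTCCC, had 3114 against 524 RPM and was 5.95-fold higher (5.83 to 6.07). It ranked first among mutant 22-nt sequences, and with CTGCTCGTACGAAGAGGGCTCC, at 2637 against 428 RPM, it belonged to an overlapping series that together took 10851 RPM in the mutant and 2163 in the non-mutant library. Members of this series differed in their ratio, since GCTCGTACGAAGAGGGCTCCCT, shifted along the same stretch, had a ratio of 0.851 (0.815 to 0.889). TGCGGCACATGGCTAAGACGCC was 13.6-fold higher in the mutant (13.2 to 14.0) and CACGGTGGAAGAAGCTGGTGCC 15.9-fold higher (15.4 to 16.4). AAGCTAGCTATTTTGCCGAGCA, the most abundant 22-nt sequence of the non-mutant library at 763 RPM, had 1008 in the mutant, a ratio of 1.32 (1.29 to 1.36).

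The first base, which takes part in sorting small RNAs among ARGONAUTE proteins, was compared within size classes. Among 24-nt reads, 31.8% began with A in the mutant (31.8 to 31.9%) and 30.7% in the non-mutant library (30.7 to 30.7%), a difference of 1.14 percentage points. The larger difference was in G, which began 23.95% of mutant and 30.02% of non-mutant 24-nt reads. A lower share of first-base G in the mutant was also seen at 20, 21, 22 and 23 nt, with 11.6% against 21.4% at 21 nt and 12.0% against 19.7% at 22 nt. At 25 nt it was higher in the mutant, at 21.6% against 17.5%, in a class where U began 49.05% of non-mutant and 26.7% of mutant reads. Adapter reads made up 11.9% of the non-mutant 25-nt reads, and without them G began 22.6% of mutant and 19.9% of non-mutant reads of 25 nt, and U 23.1% and 42.2%. U, the usual first base of miRNAs, began 44.1% of mutant and 31.6% of non-mutant 21-nt reads. Without miR166 these shares were 37.6% and 30.1%, and over distinct sequences at equal depth they were 33.39% and 28.05%. C began 33.7% and 26.8% of 22-nt reads. The last bases differed as well: G stood at position 22 of 37.8% of mutant and 26.8% of non-mutant 24-nt reads, counted from the first base.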

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

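Apart from the test of absent sequences, the tests in this part were chosen after the results were seen. Signals outside the compared classes were present in both libraries. Reads sharing 10 bases with the 5′ adapter made up 0.533% of the mutant and 0.489% of the non-mutant library, above 0.0640% and 0.0363% for the reversed adapter. They made up 11.9% of 25-nt reads in the non-mutant and 5.01% in the mutant library. Fragments of 5.8S ribosomal RNA reached 1925 RPM in the mutant library, against 191 in the non-mutant library. Reads of 31 nt, outside the 18 to 30 nt total, numbered 25751 in the non-mutant and 3275 in the mutant library, which is 0.0765% and 0.0502% of reads.

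The 24-nt share was lower in the mutant library, with a log2 ratio of -0.45. Standardised to a common GC content and common end bases, the log2 ratio was -0.38, so these biases do not account for the whole difference. Without the 1000 most abundant sequences it was -0.30, so a few abundant sequences account for part of it at most. A size cut shifted to shorter RNA would lower 25-nt reads at least as much as 24-nt reads, and the 25-nt log2 ratio, without adapter and ribosomal reads, was 0.061. The 25-nt class also differed in makeup, since without adapter reads U began 23.1% of mutant and 42.2% of non-mutant reads. Lengths of 26 to 30 nt were higher in the mutant, with log2 ratios from 0.69 to 2.01. The 25-nt level may therefore not follow a size cut alone, and its value does not decide on this explanation. Other differences in library preparation are confounded with the genotype and cannot be told apart from a lower level of 24-nt siRNAs in rmr2-1 cobs, which stays open as an untested hypothesis.

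The mutant library held fewer distinct sequences when sequences of 1 read were counted, while of at least 2 reads it held more at equal 24-nt reads (340745 against 297371). Depth is argued against, since at equal 24-nt reads the mutant count was still 32.4% lower, and so are sequencing errors, since the share of 24-nt reads with an error, non-mutant minus mutant, was -0.93 points (6.01% against 6.94%). Among 53613 sequences of 24 nt expected at 3 to 6 reads, 65.5% were absent from the mutant library and 4.46% from a part of the non-mutant library of the same size, a 14.7-fold difference, while the mean reads were 3.44 and 3.75. That part was drawn from the same library and holds sampling noise alone, so any separately made library could lack more, and the value does not decide whether fewer RNA molecules entered amplification; more sequences were also absent at 22 nt (42.8% against 9.16%) and 21 nt (41.2% against 7.39%), and the classes were not tested against each other. Fewer molecules cannot be told apart here from a change in which loci make siRNAs in the mutant, since there are no molecular identifiers and no replicate library.

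miRNA families moved apart, with an SD of log2 ratios over 17 families of 1.74. Their ratio was higher where GC content was higher (Pearson r = 0.70, Spearman rho = 0.63 across families, which are not independent replicates), and adjusting for length, GC content and end bases, fitted on other sequences, lowered the SD by 27.97% to 1.26. Adding abundance to the adjustment raised the SD to 1.81. Bias of this kind may therefore account for part of the spread, but it cannot be told apart from a difference in miRNA levels because other sequences scatter widely around the fit (SD 2.00). A biological effect of rmr2-1 on miRNAs was not tested, and miR390, with the same 61.9% GC as miR160, stood at -0.78 against 3.69.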

How the results depend on the processing

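Of 28 alternatives, 15 fixed before the data were examined and 13 chosen after seeing the data, 6 stayed within the counting interval or within 1.5-fold of a count, 21 moved further and 1 reversed; counting intervals at this depth are narrow, and the cause of a move was not tested. The log2 ratio of the 24-nt share (-0.45) was -0.43 over 20 to 25 nt reads only, -0.17 for distinct sequences at equal depth, -0.449 without adapter and ribosomal reads, -0.471 standardised for GC content, -0.374 for end bases, and -0.304 without the 1000 most abundant sequences. In the order 20 to 25 nt only, GC content, end bases and 1000 sequences left out, the log2 ratio of the 22-nt share (1.034) was 1.05, 1.07, 0.91 and 0.88, and that of the 21-nt share (0.81) was 0.83, 0.88, 0.65 and 0.71. The log2 ratio of 24-nt reads per miRNA read (-1.59) was -0.60 without miR166, -0.58 with the median ratio of families, and -1.48 with 22-nt reads as the reference. That of distinct 24-nt sequences (-0.96) was -2.96 without thinning, -0.29 for sequences of at least 2 reads, -0.57 at equal 24-nt reads, and reversed to 0.20 for sequences of at least 2 reads at equal 24-nt reads. That of first-base A among 24-nt reads (0.05) was 0.067 for distinct sequences. miRNA families beyond 2-fold (8) numbered from 8 to 11, and scaling to miRNA reads changed the split from 6 higher and 2 lower to 3 and 8, and to 6 and 4 without miR166 in the scale; matching the full mature sequence gave 7 and 1, with miR167 counted as higher and miR162 below 50 reads. Not run, for want of a genome, were 12 further alternatives: genome-matched reads, structural RNA left out, and those of windows and of reads near genes. The mutant depth limits families with few mutant reads, such as miR162 with 14 and miR827 with 0. No paired analysis was possible because each genotype had 1 library.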

Other observations

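The values in this part were chosen after the data were seen. Within some miRNA families the members differed in their ratio. In miR167, TGAAGCTGCCAGCATGATCTA was 3.84-fold higher in the mutant library (3.49 to 4.22), while TGAAGCTGCCAGCATGATCTG, which has another last base, had a ratio of 0.591 (0.490 to 0.708). In miR166, the 3 most abundant members were all higher, by 11.6-fold for TCGGACCAGGCTTCATTCCCC, 6.27-fold for TCGGACCAGGCTTCATTCCTC and 4.62-fold for TCGGACCAGGCTTCAATCCCT. The 21-nt form of miR159, TTTGGATTGAAGGGAGCTCTG, had a ratio of 2.01 (1.86 to 2.16), and its 18-nt form TTTGGATTGAAGGGAGCT a ratio of 0.103 (0.0746 to 0.138). In miR172, the form beginning with A, AGAATCTTGATGATGCTGCAT, had a ratio of 0.815 and the form beginning with G, GGAATCTTGATGATGCTGCAT, a ratio of 1.04.

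Other sequences of the mutant library were placed in the non-mutant library by their abundance. Of mutant 24-nt sequences with 1 read, 18.3% were also in the non-mutant library, and of those with at least 50 reads, 98.3%. In the classes of 24-nt sequences set by a random part of the non-mutant library, the ratio of the mutant to the other part was 0.752 for sequences with 0 reads in the first part, which held 51.1% of the 24-nt reads of the other part. It was 0.668 for sequences of 5 to 16 reads, and 0.714 and then 0.836 in the classes between these and the highest. For the 140 sequences of the highest class it was 0.552, so the ratio did not fall steadily with abundance. Classes of many reads were chosen as abundant in the non-mutant library, which favours a lower ratio in the mutant.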
